A study of Oryza sativa Japonica Group and Oryza sativa Indica Group with 24 samples.

How the data were processed

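Total RNA from the crown and growing point of rice plants at panicle initiation was measured on 24 Affymetrix rice arrays, each with biotin-labelled RNA of 1 sample, per the labels' protocols. The titles give 4 sets of 6 arrays, with 3 unstressed (control) and 3 salt-stressed arrays in each. A set is named m103 (a japonica cultivar that the series text calls sensitive), a set is named agami (a japonica cultivar that it calls tolerant), and both other sets carry the name ir29 and repeat the replicate numbers. The series text names ir29 as a sensitive indica and ir63731 as a tolerant indica, and no title carries the latter. The ir29-labelled sets were therefore kept apart by the number in the title as a first set (numbers 7 to 12) and a second set (numbers 19 to 24), and neither was given a tolerance class. The labels' description calls all samples unstressed, so control and salt were taken from the titles, which the treatment field of the labels matches. The titles call the replicates biological. How many plants a sample holds, the salt level and the length of the stress are not given in the sources used here.

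The deposited table gives an intensity on a linear scale for 57381 probe sets per array, made with GCOS 1.2 per the submitters' processing notes. The signal algorithm and any masking are not given in the sources used here. The arrays did not share a scale. The mean after leaving out the lowest and highest 2% of probe sets was between 500.07 and 500.08 in 15 arrays and between 58.79 and 115.7 in the other 9, which are 5 of m103 and 4 of the first ir29-labelled set. The plan was to use the values as deposited if they shared a scale. Because they did not, each array was multiplied so that this trimmed mean was 500, which is what the 15 arrays already had. The values were then taken as log2(scaled signal + 16). Fold changes on this scale understate the change of dim probe sets. The 123 control probe sets were left out. Of the remaining 57258 probe sets, the 34355 with a mean log2 value above the 40th percentile were tested, which corresponds to a scaled signal of about 27.9. Pearson's r between replicate arrays was 0.963 to 0.974. The ratio of the actin 3' to 5' control probe sets, a sign of RNA integrity and labelling, ran from 4.11 to 10.1. With 3 arrays per group, the number of arrays limits the precision.

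Tests were made with limma 3.58.1 in R 4.3.3. A model with 1 mean for each of the 8 groups was fitted to all 24 arrays, so that the groups share an estimate of spread, and contrasts were tested two-sided with moderated statistics that follow the intensity trend. The contrasts were salt against control in each set, the mean of these 4 effects, the difference in salt effect between agami and m103, between the second and first ir29-labelled sets and between the ir29-labelled sets and the japonica cultivars, and the same 3 comparisons among control arrays. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested. Errors given with log2 changes are standard errors from this model, and scaled signals are given with the SD over 3 arrays. The replicate number did not enter the model. Figures were drawn with matplotlib 3.10.9.

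The platform's annotation, which is old, gave 1 gene for 22436 probe sets, several for 95 and none for the other 34850. Gene IDs were looked up in the RefSeq gene table of assembly ASM3414082v1, which held all 22436 and was used for names only. Coordinates are not given because the genome build behind the probes is not given in the sources used here. An informative name was found for 3192 probe sets of 2457 genes, of which 2850 probe sets of 2272 genes were tested. Most called probe sets therefore stay unnamed here. Among the 50 largest rises in m103 that separated all salt from all control arrays, 39 had a gene and 11 a name. Names are symbols of the reference, with the gene ID added where symbols repeat.

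The design, the alternatives, the rule for named genes and 33 gene lists were set before the data were examined. The lists relied on gene descriptions and locus names that the annotation lacks, so they matched few genes. They were replaced by 53 lists built from gene symbols after the annotation had been read and before any test was made, and the salt-stress genes fixed by locus were looked up by symbol, which gave 20 with a probe set and 18 tested. Lists meant as markers for leaf (photosynthesis and chlorophyll), root (Casparian strip proteins and the related CASPL genes) and seed (storage proteins) were included. How well the root list marks root tissue was not tested. Lists were tested with limma's cameraPR on the moderated statistics of named genes, with 1 probe set per gene (the highest mean signal), a preset correlation of 0.01 and adjustment over the 53 lists. All lists held at least 5 measured genes. The same lists were tested with an estimated correlation and with fry. Genes were named if they passed the threshold, had a name and showed no overlap between salt and control arrays, taking the 10 largest rises and falls per set. For the mean of the sets, no overlap was required within each of the 4 sets, a reading adopted when the rule was coded. For differences and control contrasts the 6 largest each way were taken without that condition. The rule also took up to 4 members of a described list and all fixed salt-stress genes, though not all of the latter are named below. Members that failed the threshold and are named beside a list were chosen after their values were seen.

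The model was tested on simulated data drawn from the real group means and spreads with about 200 changed probe sets per comparison. For m103 it recovered 14.1% of changes of 0.5 (log2), 55.2% of changes of 1 and 75.4% of changes of 2, with 5 false calls among 34355 probe sets. For agami the shares were 20%, 47.5% and 78.4% with 8 false calls. For the first ir29-labelled set they were 21.8%, 54.5% and 79.7% with 4 false calls, and for the second set 14.5%, 44.8% and 88.5% with 4 false calls. The real data had more calls in every set (321 in agami to 3039 in m103), and the adjusted threshold depends on how many probe sets change. The simulated deviations were also drawn independently for each probe set. These shares and false calls therefore need not hold for the real comparisons. Settings varied were other pseudocounts, filters, normalizations (quantile, and centring on the median), variance models, a replicate block, a fit on only the sets compared, leaving out each array in turn, and treating ir29 as 1 group. Settings chosen after seeing the data were the scaling state of an array as a covariate, the replicate number as a block over all sets for the salt contrasts, no arrays numbered 1, and only unscaled arrays in m103 and the first ir29-labelled set.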

Results

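The arrays measured transcripts in crown and growing point tissue, which holds the shoot meristem, of rice at the start of panicle formation, when the plant is sensitive to salt. Each of the 4 sets (m103, agami, and the first and second ir29-labelled sets) had 3 control and 3 salt arrays. Sets of arrays, not single conditions, made up most of the variation. The first principal component (40.2% of the variance) parted the ir29-labelled sets from the japonica cultivars. The second (12.7%) parted m103 and the first ir29-labelled set from agami and the second, and the fourth (4.94%) put salt arrays above the control arrays of their own set. The first 2 of these sets also hold all 9 arrays that were deposited unscaled, but their 3 scaled arrays lie with their own sets on the second component (55.1, 36 and 60.8, with every agami and second-set array below 0). The third (10%) parted m103 and the second ir29-labelled set from agami and the first. Salt was compared only within sets.

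**Figure D1:**
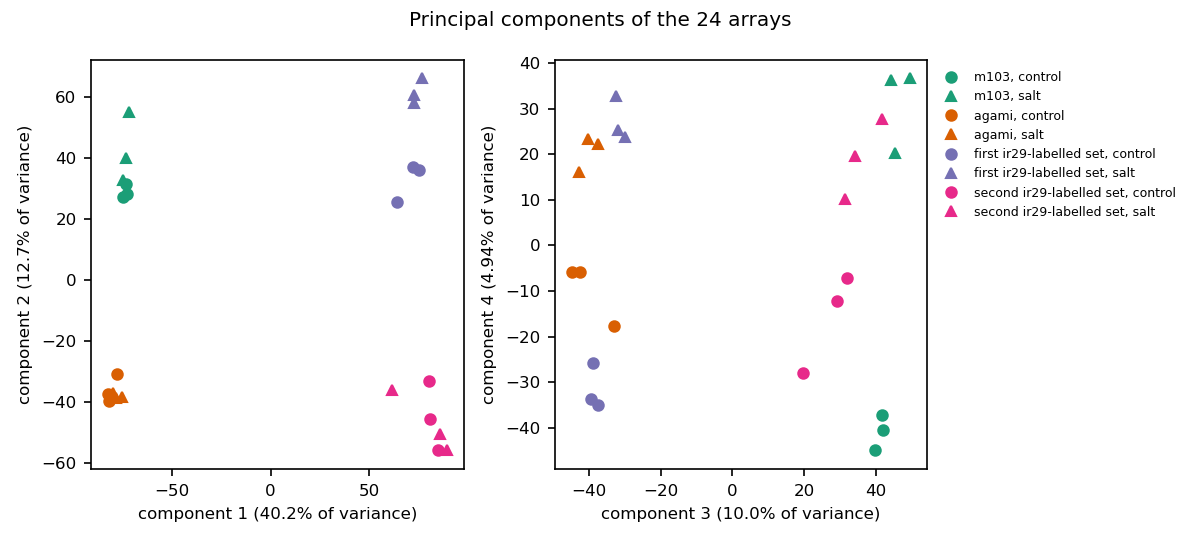
Scores of the 24 arrays on principal components 1 and 2 (left) and 3 and 4 (right), with the share of variance on each axis, colour for the set, circles for control and triangles for salt. Component 1 (40.2%) parts the ir29-labelled sets from m103 and agami, and on component 4 (4.94%) each set's salt arrays lie above its control arrays.

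In m103, the japonica cultivar called sensitive, the largest rises of named genes included chitinases, single glutaredoxins and a metallothionein. Cht1, a chitinase, rose from a scaled signal of 97.3 ± 64.9 to 11600 ± 3910 (SD, n = 3), a log2 change of 6.79 ± 0.44 (limma adjusted p = 6.5e-10). The glutaredoxins GRXC1 (5.22 ± 0.44), GRXC10 (3.94 ± 0.42) and GRXC15 (3.31 ± 0.34) rose too, while the list of 32 glutaredoxins and thioredoxins did not stand apart (3 rose and 1 fell, 5 and 1 adjusted over the list alone, list adjusted p = 0.19). PBZ1, a pathogenesis-related protein (5.07 ± 0.75), NSHB1, a non-symbiotic haemoglobin (4.11 ± 0.46), and CIPK14, a kinase of calcium signalling (3.69 ± 0.22), were also higher. ALN, the allantoinase of purine breakdown, fell from 3640 ± 199 to 1200 ± 165 (log2 change -1.60 ± 0.10, adjusted p = 6.5e-10). The silicon channel NIP2-1 (-1.84 ± 0.28), the aquaporin TIP4-1 (-1.5 ± 0.31) and the potassium transporter HAK22 (-1.91 ± 0.46) also fell. In all, 1433 probe sets were higher with salt and 1606 lower, of which 419 and 460 changed at least 2-fold.

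Among gene lists in m103, 8 of 21 genes for chitinases, germins and defence rose, 2 fell and 11 did not pass (11 rose and 2 fell when adjusted over the list alone). Cht11 (2.80 ± 0.32) and Cht3 (2.15 ± 0.52) were among the rises. The cameraPR adjusted p was 0.0021, and adjusted p = 0.38 with an estimated correlation. Of 7 LEA proteins and dehydrins, which protect cells from drying, 5 rose (5 adjusted over the list alone), led by RAB21 (2.63 ± 0.25) and PM19L (1.91 ± 0.44; list adjusted p = 0.0057, and adjusted p = 0.38 with an estimated correlation). MT4A (3.72 ± 0.30) and MT2A (1.60 ± 0.18) rose among 7 metallothioneins (2 adjusted over the list alone, list adjusted p = 0.0021, and adjusted p = 0.38 with an estimated correlation). Of 22 heat shock proteins 4 rose, CLPB1 by 2.05 ± 0.24 and HSP24.1 by 1.81 ± 0.39 among them, and HSP18.8 fell by 0.89 (5 and 1 adjusted over the list alone, list adjusted p = 0.022, and adjusted p = 0.50 with an estimated correlation). Cytosolic ribosomal proteins rose in 7 of 25 genes (13 adjusted over the list alone), RPS7 by 0.38 ± 0.099 (list adjusted p = 0.0021, and adjusted p = 0.47 with an estimated correlation). The DNA replication genes FEN1B (0.59 ± 0.13) and RPA32-2 (0.47 ± 0.096) rose among 30 (3 adjusted over the list alone, list adjusted p = 0.022, and adjusted p = 0.47 with an estimated correlation).

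Some cellulose and lignin genes fell in m103, and most did not pass. Of 25 cellulose synthases and related genes 6 fell and CSLA9 rose (8 fell and 1 rose adjusted over the list alone). The secondary wall synthases CESA7 (-1.14 ± 0.24), CESA4 (-0.75 ± 0.20) and CESA8 (-0.66 ± 0.13) fell (list adjusted p = 0.0021, and adjusted p = 0.38 with an estimated correlation). Of 23 lignin and phenylpropanoid genes 6 fell and none rose (8 fell adjusted over the list alone), including LAC10 (-1.21 ± 0.28) and CAD3 (-0.92 ± 0.16; list adjusted p = 0.0038, and adjusted p = 0.38 with an estimated correlation). The list meant as a root marker moved with them. Of its 22 Casparian strip proteins and related CASPL genes 6 fell and 2 rose (8 and 3 adjusted over the list alone). CASPL2C1 was at -1.44 ± 0.23 and CASPL2A1 at -0.70 ± 0.13 (list adjusted p = 0.040, and adjusted p = 0.38 with an estimated correlation). Of 24 calmodulins and related genes 5 fell and 1 rose (7 and 2 adjusted over the list alone), CML9 at -0.82 ± 0.18 and CML29 at 0.97 ± 0.21 (list adjusted p = 0.040, and adjusted p = 0.38 with an estimated correlation). The m103 count of 3039 was 1756 without salt replicate 2, 1757 without control replicate 1 and 2019 without control replicate 3. With only the 5 unscaled m103 arrays it was 2373.

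**Figure D2:**
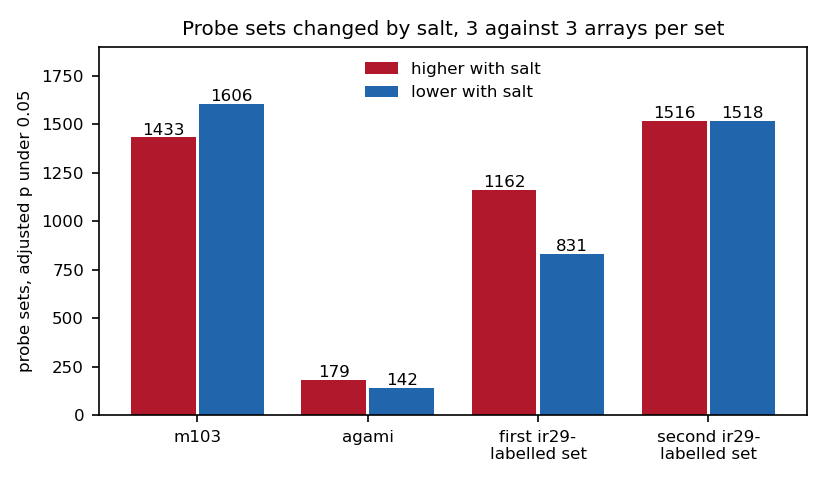
Number of probe sets higher (red) and lower (blue) with salt in each set, at a limma adjusted p under 0.05 among 34355 tested, from 3 salt and 3 control arrays per set. The bars run from 142 lower in agami to 1606 lower in m103.

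In agami, the japonica cultivar called tolerant, fewer probe sets were called. RAB21, a dehydrin that responds to abscisic acid, rose from 106 ± 5.64 to 481 ± 10.6 (log2 change 2.03 ± 0.25, adjusted p = 2e-04). The sugar transporter SWEET15 (1.94 ± 0.27) and the actin-binding ADF5 (0.93 ± 0.13) rose as well. ALN fell by 0.88 (SE 0.10, adjusted p = 8.1e-05), from 5240 ± 199 to 2840 ± 126, and HSFB2C, a heat shock factor, fell from 791 ± 32.6 to 191 ± 72.2 (log2 change -2.03 ± 0.36). Cht1 rose by 2.41 ± 0.44 (adjusted p = 0.010), a call that ended without control replicate 2 (adjusted p = 0.062), salt replicate 2 (adjusted p = 0.059) or salt replicate 3 (adjusted p = 0.055). HSP24.1 fell by 1.96 (SE 0.39, adjusted p = 0.017), a call that ended without control replicate 2 (adjusted p = 0.083) or any 1 salt array (adjusted p = 0.053 to adjusted p = 0.063).

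Lists in agami gave 3 calls among 53. Of 7 LEA proteins and dehydrins 2 rose, RAB21 and RAB16B (1.39 ± 0.33), and 5 did not pass (2 adjusted over the list alone, list adjusted p = 0.037, and adjusted p = 0.52 with an estimated correlation). The call of RAB16B ended when any 1 agami array was left out. Of 25 cytosolic ribosomal proteins 2 rose (6 adjusted over the list alone), RPL11 by 0.32 ± 0.079, and the list median was 0.21, or 0.12 with quantile normalization (list adjusted p = 7.3e-08, and adjusted p = 0.52 with an estimated correlation). None of 28 jasmonate genes passed alone, also when adjusted over the list alone, while the list lay lower (median -0.35, list adjusted p = 0.036, and adjusted p = 0.53 with an estimated correlation), with JAZ13 at -2.03 and JAZ10 at -1.82. In all 179 probe sets were higher and 142 lower, and with arrays centred on their medians the share of higher calls was 68.5% in place of 55.8%. The total of 321 was 77 without control replicate 3, 91 without control replicate 2, 80, 111 and 159 without salt replicates 2, 3 and 1. It was 119 without the intensity trend, 200 without the filter, 213 from the agami arrays alone and 597 without the arrays numbered 1.

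In the first ir29-labelled set, the largest rises of named genes included chitinases and a dehydrin. Cht11, a chitinase, rose from 45.8 ± 23 to 1700 ± 250 (log2 change 4.85 ± 0.32, adjusted p = 2.3e-09) and PBZ1 from 703 ± 57.1 to 14600 ± 2160 (4.33 ± 0.75). RAB21 rose from 165 ± 58.6 to 2520 ± 580 (3.83 ± 0.25, adjusted p = 2.3e-09). The transporters ABCG45 (4.32 ± 0.73) and HAK17 (3.42 ± 0.28), the lectin gene salT (3.42 ± 0.69 for 1 probe set and 3.13 ± 0.65 for the brighter) and WRKY62 (3.17 ± 0.50) rose by more than 3 on the log2 scale. ALN fell by 1.68 (SE 0.10), and GI, a clock gene, fell from 2150 ± 726 to 764 ± 475 (-1.63 ± 0.35, adjusted p = 0.0051). In all 1162 probe sets were higher and 831 lower, and of those that changed at least 2-fold 604 were higher and 129 lower.

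Lists in that set gave 11 calls. Of 21 genes for chitinases, germins and defence 8 rose and 13 did not pass (10 rose adjusted over the list alone), RBBI3.3, a protease inhibitor, by 2.85 ± 0.24 (list adjusted p = 7.6e-09, and adjusted p = 0.13 with an estimated correlation). Of 5 WRKY factors 2 rose, WRKY62 and WRKY76 (2.68 ± 0.44; 3 adjusted over the list alone, list adjusted p = 0.019, and adjusted p = 0.31 with an estimated correlation). Of 7 NAC factors 4 rose, NAC5 by 1.36 ± 0.25 and NAC067 by 2.16 ± 0.54 (4 adjusted over the list alone, list adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation). Of 28 cytokinin genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), among them the response regulators RR9 (1.21 ± 0.20) and RR4 (1.07 ± 0.17; list adjusted p = 0.019, and adjusted p = 0.31 with an estimated correlation). Of 24 expansins, which loosen walls, 8 rose and 3 fell (9 and 3 adjusted over the list alone), EXPB6 at 1.28 ± 0.16 and EXPA1 at -1.07 ± 0.30 (list adjusted p = 0.044, and adjusted p = 0.34 with an estimated correlation). Of 7 metallothioneins 3 rose (3 adjusted over the list alone), MT4A by 1.73 ± 0.30 (list adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation). Of 7 LEA proteins and dehydrins RAB21 and RAB16B (2.86 ± 0.33) rose and EM fell by 1.27 (3 rose and 1 fell adjusted over the list alone, list adjusted p = 5.9e-04, and adjusted p = 0.35 with an estimated correlation).

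Some clock, cell cycle and cellulose genes fell there. GI, PRR95 (-1.16 ± 0.21), PRR37 (-0.82 ± 0.19) and PRR73 (-0.72 ± 0.17) fell among 9 clock and photoperiod genes (4 adjusted over the list alone, list adjusted p = 0.019, and adjusted p = 0.31 with an estimated correlation). Of 25 cellulose synthases and related genes 5 fell and CSLE1 rose (6 and 1 adjusted over the list alone), CESA5 at -0.60 ± 0.10 (list adjusted p = 0.033, and adjusted p = 0.44 with an estimated correlation). Of 49 cyclins, CDKB and kinesins 3 fell (5 adjusted over the list alone), KIN8B by 0.41, with a list median of -0.17 (list adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). With arrays centred on their medians the median of all probe sets moved from 0.008 to -0.103 and the share of higher calls from 58.3% to 32.2%. Against that shift the expansin median of 0.25 became 0.14, the cytokinin median of 0.21 became 0.10 and the cyclin median became -0.29, with no sign turned. The total of 1993 calls was 1038 with only the 4 unscaled arrays, 2 per condition.

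In the second ir29-labelled set, Cht1 rose from 131 ± 66.6 to 3380 ± 2010 (log2 change 4.40 ± 0.44, adjusted p = 5.6e-06). RAB21 (2.37 ± 0.25), SWEET15 (2.35 ± 0.27), the aquaporin PIP1-3 (1.2 ± 0.23) and DAO, which inactivates auxin (1.2 ± 0.13), rose as well. Single heat shock genes fell, with HSP24.1 going from 4720 ± 2510 to 768 ± 18.2 (-2.41 ± 0.39, adjusted p = 9e-04), HSP17.4 at -2.29 ± 0.43, and the factors HSFB2C (-1.73 ± 0.36), HSFA2C (-1.69 ± 0.28) and HSFB2B (-1.68 ± 0.34). In all 1516 probe sets were higher and 1518 lower, but only 124 and 205 of them changed at least 2-fold.

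Of 22 heat shock proteins there 5 fell, none rose and 17 did not pass (5 fell adjusted over the list alone, list adjusted p = 0.0062, and adjusted p = 0.73 with an estimated correlation). Of 19 heat shock factors 5 fell (5 adjusted over the list alone, list adjusted p = 0.0062, and adjusted p = 0.38 with an estimated correlation). Of 30 DNA replication genes 6 rose (9 adjusted over the list alone), the sliding clamp PCNA by 0.61 ± 0.099 and the helicase subunit MCM5 by 0.53 ± 0.10 (list adjusted p = 0.018, and adjusted p = 0.74 with an estimated correlation). Of 25 cytosolic ribosomal proteins 10 rose (15 adjusted over the list alone), RPS15 by 0.46 ± 0.090, with a list median of 0.29, or 0.19 with quantile normalization (list adjusted p = 2.1e-05, and adjusted p = 0.62 with an estimated correlation). Of 10 growth-regulating factors 4 rose (5 adjusted over the list alone), GRF10 by 0.57 ± 0.11 (list adjusted p = 0.039, and adjusted p = 0.62 with an estimated correlation). Among 7 LEA proteins and dehydrins RAB21 and rab25 (0.77 ± 0.23) rose (3 adjusted over the list alone, list adjusted p = 0.0062, and adjusted p = 0.62 with an estimated correlation). The actin 3' to 5' ratio was 10.1 and 9.34 in salt replicates 2 and 3 of this set, the highest of the 24 arrays. The total of 3034 calls was 928 without salt replicate 2 and 1412 without control replicate 1. It was 179 when the 6 arrays were fitted alone, and the share of higher calls was 65.8% with median centring in place of 50%.

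**Figure D3:**
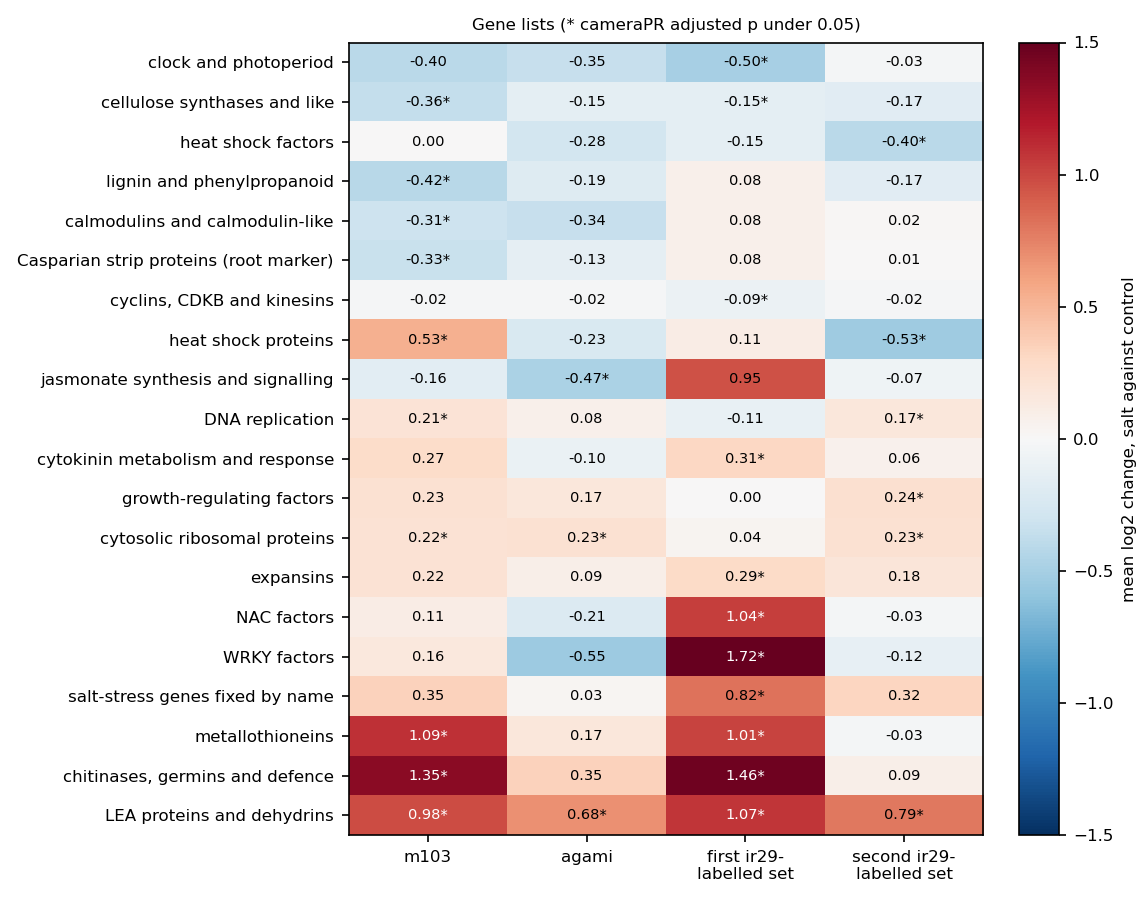
Mean log2 change with salt (colour and number) of the gene lists (rows) called in at least 1 of the 4 sets (columns), with an asterisk at a cameraPR adjusted p under 0.05. LEA proteins and dehydrins are higher in every set (0.98, 0.68, 1.07 and 0.79), and heat shock proteins are at 0.53 in m103 and -0.53 in the second ir29-labelled set; no median of a called list turned sign under quantile normalization or median centring, and no call holds with an estimated correlation.

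Averaged over the 4 sets, Cht1 rose by 4.20 ± 0.22 (adjusted p = 8.1e-12) and RAB21 by 2.71 ± 0.13 (adjusted p = 7.8e-13), with no overlap of salt and control arrays in any set. GRXC15 (2.14 ± 0.17), CIPK14 (1.82 ± 0.11), SWEET15 (1.71 ± 0.13), RBBI3.3 (1.63 ± 0.12), ADF5 (1.0 ± 0.063) and DAO (0.94 ± 0.066) rose in the same way. ALN fell by 1.23 (SE 0.052, adjusted p = 1e-13), GI by 1.19 (SE 0.17), the kinase CIPK10 by 1.0 (SE 0.13), TPP4, a trehalose phosphatase, by 0.86 (SE 0.11), and MGD3, an enzyme of galactolipid synthesis, by 0.57 (SE 0.051). The mean effect was called in 3147 probe sets that were higher and 2950 that were lower.

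Lists gave 8 calls for the mean of the sets. Of 25 cellulose synthases and related genes 13 fell and 1 rose (15 and 1 adjusted over the list alone), CESA7 at -0.68 ± 0.12 and CESA8 at -0.44 ± 0.063 (list adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). Of 25 cytosolic ribosomal proteins 17 rose (21 adjusted over the list alone), by a median of 0.19, or 0.12 with quantile normalization (list adjusted p = 3.2e-05, and adjusted p = 0.34 with an estimated correlation). Of 24 expansins 10 rose and 1 fell (10 and 1 adjusted over the list alone), EXPB7 at 0.63 ± 0.057 (list adjusted p = 0.046, and adjusted p = 0.27 with an estimated correlation). Chitinases, germins and defence rose in 8 of 21 genes and fell in 1 (8 and 1 adjusted over the list alone, list adjusted p = 3.2e-05, and adjusted p = 0.27 with an estimated correlation). LEA proteins and dehydrins rose in 4 of 7 (4 adjusted over the list alone, list adjusted p = 3.2e-05, and adjusted p = 0.27 with an estimated correlation). Metallothioneins rose in 2 of 7 (3 adjusted over the list alone, list adjusted p = 0.026, and adjusted p = 0.34 with an estimated correlation). Of 9 clock and photoperiod genes 4 fell and CCA1 rose (5 and 1 adjusted over the list alone, list adjusted p = 0.046, and adjusted p = 0.27 with an estimated correlation). The leaf marker list did not stand apart from other genes with salt, with 3 of 25 members higher and 2 lower for the mean of the sets and a median of -0.04 in m103, 0.07 in agami, 0.03 in the first and -0.03 in the second ir29-labelled set, with adjusted p = 0.62 the smallest. The seed marker list had medians of 0.23, -0.21, -0.05 and -0.27 in the same order, with adjusted p = 0.49 the smallest. The root marker list was at a median of -0.08 in agami, -0.02 in the first and -0.10 in the second ir29-labelled set, with adjusted p = 0.28 the smallest of these.

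**Figure D4:**
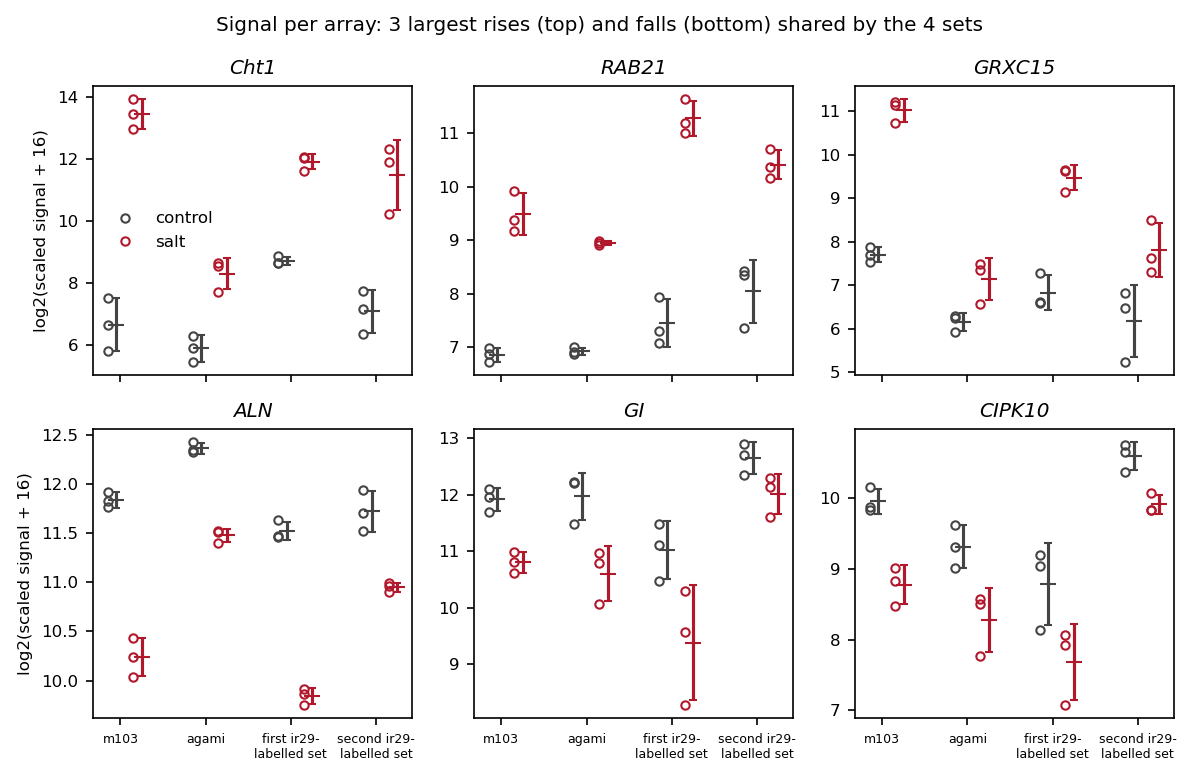
Log2(scaled signal + 16) of each array (circles; grey control, red salt) with the mean and SD of 3 arrays, for the 3 largest rises (Cht1, RAB21, GRXC15) and falls (ALN, GI, CIPK10) of the mean over sets, in the 4 sets. The mean log2 changes were 4.20 for Cht1, 2.71 for RAB21, 2.14 for GRXC15, -1.23 for ALN, -1.19 for GI and -1.0 for CIPK10.

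Of the 18 salt-stress genes fixed by name, RAB21 and P5CS1, a proline synthesis enzyme, rose in every set. P5CS1 changed by 0.43 ± 0.078 in m103, 0.34 ± 0.078 in agami (adjusted p = 0.037), 0.29 ± 0.078 in the first (adjusted p = 0.026) and 0.34 ± 0.078 in the second ir29-labelled set (adjusted p = 0.0091). Its call in agami ended without any 1 of the 6 arrays, at adjusted p = 0.072 to adjusted p = 0.14, and so did that of RAB16B there, at adjusted p = 0.073 to adjusted p = 0.16. In the first set the call of P5CS1 ended without control replicates 1 or 2 or salt replicates 2 or 3, at adjusted p = 0.10 to adjusted p = 0.13, and in the second set without control replicate 1 (adjusted p = 0.055). RAB16B rose in m103 (1.26 ± 0.33), agami (1.39 ± 0.33) and the first set, and in the second set was at 1.02 with adjusted p = 0.052. Its call in m103 ended without control replicate 2 (adjusted p = 0.066) or salt replicates 1 (adjusted p = 0.083) or 2 (adjusted p = 0.064). NAC5, a stress-induced factor, rose in m103 (1.61, adjusted p = 2.1e-04) and in the first set. The lectin gene salT rose in the first set alone by the test, and in m103 was at 1.77 ± 0.65 (adjusted p = 0.10), while without salt replicate 3 it was 2.96 (adjusted p = 3.7e-04). NAC6 (1.84 ± 0.52, adjusted p = 0.037) and BZIP23 (0.89, adjusted p = 0.0039) rose in the first set, the former at adjusted p = 0.085 to adjusted p = 0.097 when any 1 array was left out. HKT1;5, a sodium transporter, was at -0.52 in m103, -0.10 in agami, 0.48 in the first and -0.16 in the second set and passed in none, like HAK5, DREB1A, DREB2A, MYB2, BADH1, TPP1 and P5CS2. As a list, 7 of 18 rose in the first set (8 adjusted over the list alone, median 0.20, or 0.09 with median centring, list adjusted p = 1.2e-04, and adjusted p = 0.13 with an estimated correlation). In m103 6 rose and none fell (9 and 4 adjusted over the list alone, list adjusted p = 0.11), and not all 6 are named here. For the mean of the sets 7 rose and AKT1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.0026, and adjusted p = 0.27 with an estimated correlation).

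Salt responses of the sets were alike in direction at called probe sets and weakly correlated over all. Of the probe sets called in 1 set, 62.1% (first ir29-labelled set, measured in agami) to 89.1% (agami, measured in m103 and in the second set) had a change of the same sign in another, called there or not. Across the 34355 probe sets, which are not independent replicates, Pearson's r of log2 changes was 0.30 between m103 and the first ir29-labelled set, 0.24 between m103 and agami and between agami and the second set, 0.19 between m103 and the second set, 0.11 between the first and second sets and 0.055 between agami and the first set. The sets share no control arrays. Without agami control replicate 1 the r of 0.24 between m103 and agami was 0.14, and the r of 0.055 was 0.091. The latter was 0.023 without agami control replicate 2 and 0.034 without control replicate 1 of the first set. In all 4 sets 34 probe sets were higher and 14 lower, against 0.011 and 0.0071 for independent lists, and 104 were called opposite ways in different sets. Agami shared 104 of its 179 higher calls with m103 (7.47 for independent lists). The sets share an estimate of spread for each probe set, so their lists need not be independent even without a common response. The numbers for independent lists are therefore too low a measure to judge the overlap by.

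The difference in salt response between agami and m103 compares 1 japonica cultivar called tolerant with 1 called sensitive, so tolerance is confounded with any other difference between these cultivars or their arrays. GRXC1 (-5.72 ± 0.62, adjusted p = 3.3e-05), NSHB1 (-4.60 ± 0.65), Cht1 (-4.39 ± 0.63) and MT4A (-3.89 ± 0.43, adjusted p = 3.3e-05) responded less in agami. The germin genes GER8 (1.40 ± 0.33) and GER4 (1.08 ± 0.21) had the higher change in agami. Heat shock proteins differed as a list (3 of 22 lower, 9 adjusted over the list alone, list adjusted p = 5.3e-05, and adjusted p = 0.84 with an estimated correlation), HSP24.1 by -3.77 ± 0.56. The cytokinin list (RR2 at -1.04 ± 0.25 and CKX11 at -0.93 ± 0.23 of 28 genes, 4 adjusted over the list alone) had adjusted p = 0.035, and adjusted p = 0.84 with an estimated correlation. The metallothioneins (MT4A alone of 7, 2 adjusted over the list alone) had adjusted p = 0.017, and adjusted p = 0.84 with an estimated correlation. In all 181 probe sets had a higher and 168 a lower change in agami, with a share higher of 63.8% after median centring in place of 51.9%. The total of 349 was 135, 151 and 215 without m103 salt replicate 2, control replicate 3 and control replicate 1. Without agami control replicates 1, 2 and 3 it was 755, 171 and 142, and without agami salt replicates 1, 2 and 3 it was 177, 230 and 218. It was 131 without the intensity trend, 213 with only unscaled m103 arrays and 571 without the arrays numbered 1.

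The second ir29-labelled set differed from the first in some of the defence genes. The salt change of Cht11 (-5.04 ± 0.45, adjusted p = 3.4e-06), PBZ1 (-4.70 ± 1.1), ABCG45 (-4.62 ± 1.0) and salT (-4.02 ± 0.98) was lower in the second set. PIN5a, an auxin carrier (1.78 ± 0.43), and SWEET15 (1.48 ± 0.38) had the higher change there. Of 21 genes for chitinases, germins and defence 7 differed downward (9 adjusted over the list alone, list adjusted p = 4.3e-05, and adjusted p = 0.38 with an estimated correlation). WRKY62 (-3.02 ± 0.71) was the only 1 of 5 WRKY factors to pass (4 adjusted over the list alone, list adjusted p = 0.021, and adjusted p = 0.38 with an estimated correlation). Of 30 DNA replication genes 3 differed upward (11 adjusted over the list alone), PCNA by 0.78 ± 0.14, with a list median of 0.32, or 0.51 with median centring (list adjusted p = 2.3e-04, and adjusted p = 0.54 with an estimated correlation). Of 25 cytosolic ribosomal proteins 3 did so too (8 up and 1 down adjusted over the list alone, median 0.23, or 0.08 with quantile normalization and 0.41 with median centring, list adjusted p = 0.0038, and adjusted p = 0.69 with an estimated correlation). CLPB1 (-1.33 ± 0.34) was among 3 of 22 heat shock proteins with a lower change (5 adjusted over the list alone, list adjusted p = 0.022, and adjusted p = 0.69 with an estimated correlation).

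For that difference 607 probe sets were higher and 598 lower in the second set. With median centring, which moved the median of all probe sets from -0.041 to 0.141, 1709 were higher and 399 lower, or 81.1% higher in place of 50.4%. The total of 1205 was 539 and 1836 without salt replicates 2 and 1 of the second set, and 655, 624 and 764 without control replicate 2, salt replicate 2 and salt replicate 3 of the first. It was 441 with only unscaled arrays of the first set, 575 from the ir29-labelled arrays alone, 625 without the intensity trend and 802 without the filter.

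Between the ir29-labelled sets and the japonica cultivars, few salt responses differed. HAK17, a potassium transporter (1.92 ± 0.28, adjusted p = 0.0023), CAT-A, a catalase (1.63 ± 0.28, adjusted p = 0.010), and VIT1.2, a vacuolar iron transporter (2.30 ± 0.45), had the higher change in the ir29-labelled sets. CLPB1, a disaggregating chaperone (-1.73 ± 0.24, adjusted p = 0.0011), and CIPK14 (-1.14 ± 0.22) had the lower change there. Heat shock proteins as a list were lower (median -0.33, CLPB1 alone of 22, with 6 lower and 2 higher adjusted over the list alone, list adjusted p = 0.025, and adjusted p = 0.69 with an estimated correlation). No member passed in the jasmonate list (median 0.37, 4 of 28 adjusted over the list alone, list adjusted p = 0.0012, and adjusted p = 0.51 with an estimated correlation), the ER chaperones (median -0.15, 2 of 16 adjusted over the list alone, list adjusted p = 0.029, and adjusted p = 0.47 with an estimated correlation) or DNA replication (median -0.13, 1 of 30 adjusted over the list alone, list adjusted p = 0.034, and adjusted p = 0.69 with an estimated correlation). Salt medians in m103, agami, the first and the second ir29-labelled set were 0.44, -0.21, 0.02 and -0.32 for heat shock proteins. In that order they were -0.13, -0.35, 0.34 and -0.15 for jasmonate genes, and 0.21, 0.09, -0.15 and 0.16 for DNA replication. Only those of ER chaperones (0.01, 0.07, -0.03 and -0.09) parted both ir29-labelled sets from both japonica cultivars. In all 45 probe sets had a higher and 28 a lower change, 61.6% higher, or 51.5% with median centring. The total of 73 was 146 without m103 salt replicate 1, 44, 48, 47 and 46 without m103 control replicates 1 and 3 and salt replicates 2 and 3, 47 without agami salt replicate 2, 44 without salt replicate 2 of the first and 48 without salt replicate 2 of the second ir29-labelled set. It was 36 without the intensity trend, 46 without a pseudocount and 152 without the arrays numbered 1.

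Without salt, agami had lower photosynthesis genes than m103. Of the 25 genes of the leaf marker list 18 were lower and none higher (20 adjusted over the list alone), with rbcS, the small subunit of Rubisco, at -2.27 ± 0.28, PORA at -1.32 ± 0.16 and PORB at -1.18 ± 0.10 (list adjusted p = 1.6e-15, and adjusted p = 0.11 with an estimated correlation). As a leaf marker, the list cannot tell a different leaf content of the samples from a difference between cultivars or arrays. H2B.10 (-2.51 ± 0.14) was the 1 of 6 histones to pass (1 adjusted over the list alone, list adjusted p = 0.0049, and adjusted p = 0.98 with an estimated correlation). Single genes differed more, such as C3H40 (6.57 ± 0.46) and METK3 (3.66 ± 0.14, adjusted p = 1.5e-14), which were higher in agami, and OsPRDA1 (-5.34 ± 0.47) and XB3 (-3.42 ± 0.31), which were lower. In all 1837 probe sets were higher and 2078 lower, and the total of 3915 was 2563 with the scaling state of the arrays as a covariate.

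Between the control arrays of the ir29-labelled sets, heat shock proteins were higher in the second set. Of 22 measured 13 were higher and none lower (17 adjusted over the list alone), with HSP18.6 at 3.86 ± 0.40, HSP16.0 at 3.0 ± 0.55, HSP24.1 at 2.56 ± 0.39 and CLPB1 at 1.77 ± 0.24 (list adjusted p = 9.2e-11, and adjusted p = 0.29 with an estimated correlation). HSP18.0 is uncertain, since 1 of its probe sets was at 3.99 ± 0.58 and another at -3.08 ± 0.41. Cytosolic ribosomal proteins were lower in 6 of 25 genes (7 adjusted over the list alone, median -0.20, or -0.10 with quantile normalization, list adjusted p = 0.040, and adjusted p = 0.86 with an estimated correlation). C3H2 (4.47 ± 0.24), APX5 (3.57 ± 0.24) and PMEI28 (3.54 ± 0.21) were higher in the second set, and Agglutinin (-4.07 ± 0.28) and VDAC1 (-3.68 ± 0.31) lower. In all 2340 probe sets were higher and 2332 lower, more calls than the 3915 between agami and m103. With only unscaled arrays in m103 and the first ir29-labelled set, which leaves fewer arrays, the order turned (3503 against 3802).

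Between the ir29-labelled sets and the japonica cultivars without salt, 5473 probe sets were higher and 5524 lower. The largest named differences were BURP17 (-9.17 ± 0.38, adjusted p = 2.9e-15), AldC-1 (-5.34 ± 0.24) and ACO1, which makes ethylene (-3.57 ± 0.092), and on the other side TAC1, which sets tiller angle (3.97 ± 0.22), and CLPB1 (3.44 ± 0.17). None of the 53 lists passed, with adjusted p = 0.15 the smallest, although 13 of 25 leaf marker genes were higher and 2 lower. Sequence differences under the probes are confounded with subspecies in this comparison. With median centring, which moved the median of all probe sets from -0.001 to 0.144, 69.3% of calls were higher in place of 49.8%, and with only probe sets above the 70th percentile the total of 10997 was 7289.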

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

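Of the tests of explanations given here, the array-by-array test of heat shock proteins and the comparison of residual spread were set before their results were seen, and the others, including the counts over other splits of the arrays, were chosen after. The contrasts and lists themselves were set before any test. The limits of both were made stricter after their values were found to lie on them, and that for the spread was later put back to the 5% set at first, so neither stands as a purely planned test.

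Salt responses that differed between sets by a test of the difference itself were singled out. For agami against m103 the named genes were GER8 (1.40), ADIPOR1 (1.33), GLU14 (1.11), AT1 (1.10), GER4 (1.08) and CAD3 (1.04), with a higher log2 change in agami. GRXC1 (-5.72), NSHB1 (-4.60), Cht1 (-4.39), GRXC10 (-4.26), MT4A (-3.89) and HSP24.1 (-3.77) had a lower one. List medians of the difference were -0.58 for heat shock proteins, -0.29 for cytokinin genes and -0.45 for metallothioneins, all with adjusted p = 0.84 with an estimated correlation. For the splits of the arrays, every part of the salt responses except the tested difference was removed first, so that salt and control arrays were exchanged under equal responses, which is an approximate test. The real labels gave 349 calls, as only 1 of 100 splits did, with 125 as the highest other. This argues against chance among the arrays within these sets. Each set stayed on its own side in the splits, so with 1 set per side chance differences between sets cannot be excluded.

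Between the second and first ir29-labelled sets, EM (1.86), PIN5a (1.78), EXPA1 (1.59), HSFC1B (1.52), SWEET15 (1.48) and APR-like1 (1.47) had the higher change in the second set. Cht11 (-5.04), PBZ1 (-4.70), ABCG45 (-4.62), salT (-4.02), Cht2 (-3.96) and BURP16 (-3.59) had the lower. List medians were 0.23 for cytosolic ribosomal proteins, -1.13 for chitinases, germins and defence, -0.61 for heat shock proteins, -1.84 for WRKY factors and 0.32 for DNA replication. None of these holds with an estimated correlation (adjusted p = 0.69, 0.38, 0.69, 0.38 and 0.54 in that order), and the ribosomal median was 0.08 with quantile normalization and 0.41 with median centring. In the same test only the real split of 100 gave 1205 calls, with 334 as the highest other. This argues against chance among the arrays within these sets. With 1 set per side, chance differences between sets cannot be excluded here either.

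Between the ir29-labelled sets and the japonica cultivars, VIT1.2 (2.30), HAK17 (1.92), CAT-A (1.63), NEK6 (0.97), STAR2 (0.94) and EXPB11 (0.66) had the higher change in the ir29-labelled sets, and CLPB1 (-1.73), CIPK14 (-1.14) and BGLU30 (-1.02) the lower. List medians were 0.37 for jasmonate genes, -0.33 for heat shock proteins, -0.15 for ER chaperones and -0.13 for DNA replication. None holds with an estimated correlation (adjusted p = 0.51, 0.69, 0.47 and 0.69 in that order), and only CLPB1 passed among their members. Except for ER chaperones, the salt medians of the single sets did not part both ir29-labelled sets from both japonica cultivars. Only the real split of 100 gave 73 calls, with 2 as the highest other, which argues against chance among the arrays within sets. These splits left each set on its own side. With so few sets per side, chance differences between sets cannot be excluded.

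Of 22 heat shock proteins in the second ir29-labelled set 5 fell with salt and 17 did not pass (list median -0.32, list adjusted p = 0.0062, and adjusted p = 0.73 with an estimated correlation), from control arrays in which 13 were higher than in the first set. A batch shared with the agami arrays stays open, because the list median differed by 0.13 between agami and m103 controls and by 1.0 between the ir29-labelled controls, but members went both ways in the former (4 higher, 2 lower, SD 0.84). A single aberrant array stays open, since leaving out control replicate 3 brought the median to -0.17, near the limit set for that reading, while the other omissions left it between -0.23 and -0.66. The fall and the high control level may have 1 source, since the same 3 control arrays enter both. A cultivar difference, if the second set is another cultivar, was not tested for this list.

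Fewer probe sets were called with salt in agami (321) than in m103 (3039). Scaling by the authors is argued against, because 2373 calls were left with only the unscaled m103 arrays. A larger spread between agami arrays is argued against too. The fit shares its estimate of spread, so such a spread could not widen the agami errors alone (median standard error 0.237 in both sets). With each set fitted on its own arrays there were 213 calls in agami and 3014 in m103. The median residual SD was only 4.73% above that of m103, and 2538 m103 calls were left with its standard errors raised by as much. A smaller change of the same probe sets is a candidate explanation, since at the probe sets called in m103 the median change in that direction was 0.19 in agami against 0.70 in m103. The value in m103 is inflated by the selection, and the other sets showed 0.27 and 0.21 there, so this is not particular to agami, and a difference in tolerance stays open as untested.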

How the results depend on the processing

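The scaling state as a covariate, the block over all sets for salt contrasts, no arrays numbered 1 and only unscaled arrays were chosen after seeing the data, and the other alternatives were planned. No gene that passed in either fit, no called list and no correlation reversed under any alternative run. The balance of higher and lower calls did. In the first ir29-labelled set it was 855 and 893 above the 70th percentile and 858 and 1809 with median centring. In agami it was 87 and 126 with only its own arrays, and for agami minus m103 53 and 78 with no intensity trend, and it also turned without most single arrays. The nearly even balance of second minus first turned under most settings. Of the gene and list results under settings other than leaving out an array, 3974 stayed on their side of the threshold, 300 lost it and 33 gained it. With 1 array left out these were 3096, 302 and 10. Direction was compared only where a gene or list passed, so genes that failed in both fits may have changed sign. Probe sets near the filter limit of 27.9 have signals close to the pseudocount, and the number of arrays limits the precision. The cause of a moved count was not tested. Where arrays were left out some counts fell and others rose, as in agami from 321 to 597 without the arrays numbered 1. Fewer arrays therefore do not explain every move.

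The replicate numbers were not taken to pair the arrays, though arrays numbered 1 deviate together. All 8 of these were negative on the first component of the residuals (-8.6 to -40.3, 10.5% of the residual variance) and the lowest of their group, with a mean correlation of 0.061. The clock gene GI was also lowest in the array numbered 1 of every group. In salt arrays 1, 2 and 3 of the first ir29-labelled set its log2 signal was 8.28, 9.58 and 10.3. Each group holds 1 array of each number, and why GI follows the number was not tested. The correlation of deviations between same-numbered control and salt arrays was -0.05 to 0.20 within sets, with no set in which all 3 were over 0.1, and not every array correlated best with its own number. Over all groups the mean was 0.029 for equal and -0.015 for other numbers. A replicate block within each set gave 541 calls in agami, 579 for agami minus m103 and 185 for ir29-labelled sets minus japonica cultivars. A block over all sets gave 571 in agami and 180 for the last. List calls with the block were 10 in agami, 6 for agami minus m103, 8 for second minus first ir29-labelled set and 10 for ir29-labelled sets minus japonica cultivars. No other count moved by over 1.5 times with a block.

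Calls in agami were 200 with no filter, 119 with no intensity trend, 213 with only the arrays compared and 597 with no arrays numbered 1. The second ir29-labelled set had 179 with only its own arrays, and the first had 1038 with only unscaled arrays. Agami minus m103 gave 131 with no intensity trend, 571 with no arrays numbered 1 and 213 with only unscaled arrays. Second minus first ir29-labelled set gave 802 with no filter, 2108 with median centring, 625 with no intensity trend, 575 with only the arrays compared and 441 with only unscaled arrays. Ir29-labelled sets minus japonica cultivars gave 46 with no pseudocount, 36 with no intensity trend and 152 with no arrays numbered 1. Among controls, agami against m103 gave 2563 with the scaling covariate, and ir29-labelled sets against japonica cultivars 7289 above the 70th percentile. Treating ir29 as 1 group without the set as a block gave 1200 calls, against 3444 for the mean of both sets and 2677 with the set as a block.

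Correlations of salt responses with no filter and with a pseudocount of 64 were 0.14 and 0.31 for m103 and agami, 0.19 and 0.37 for m103 and the first ir29-labelled set, 0.12 and 0.24 for m103 and the second, 0.025 and 0.08 for agami and the first, 0.14 and 0.34 for agami and the second, and 0.061 and 0.16 for the ir29-labelled sets. With 1 array left out they were 0.14 (without agami control replicate 1) to 0.26, 0.21 to 0.35, 0.14 to 0.19, 0.023 to 0.091 (without agami control replicates 2 and 1; 0.034 without first control replicate 1), 0.18 to 0.25 and 0.081 to 0.13 in that order.

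With an estimated correlation 0 lists were called in every comparison. Fry was read for whether a list moves in 1 direction, without setting it against other genes. With it, lists called were 25 in m103, 0 in agami, 22 in the first ir29-labelled set and 32 for the mean. They were 0 for agami minus m103, 9 for second minus first and 1 for ir29-labelled sets minus japonica. In the 3 control comparisons they were 6, 12 and 18. The mixed form of fry, which takes changes in either direction, passed some lists in agami and not others. Its adjusted p was 4.6e-10 for sucrose metabolism and sugar transport and 0.66 for MADS-box factors. Quantile normalization gave 5 for the mean, without clock and photoperiod genes, expansins and metallothioneins. With all named probe sets there were 6 in agami, 5 for agami minus m103, 10 for second minus first, 16 for ir29-labelled sets minus japonica and 6 between ir29-labelled controls.

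With each array left out, calls ran from 1756 (salt 2) to 2579 in m103, also 1757 (control 1) and 2019 (control 3); from 77 (control 3) to 370 in agami, also 91 (control 2), 80, 111 and 159 (salt 2, 3 and 1); from 1337 to 1542 in the first and from 928 (salt 2) to 3750 in the second ir29-labelled set, also 1412 (control 1); and from 5448 to 6355 for the mean. Agami minus m103 ran from 135 (m103 salt 2) to 755 (agami control 1), also 151 and 215 (m103 controls 3 and 1), 142 and 171 (agami controls 3 and 2) and 177, 230 and 218 (agami salt 1, 2 and 3). Second minus first ran from 539 (second salt 2) to 1836 (second salt 1), also 655, 624 and 764 (first control 2, salt 2 and salt 3). Ir29-labelled sets minus japonica ran from 44 (m103 control 1, first salt 2) to 146 (m103 salt 1), also 46 and 47 (m103 salt 3 and 2), 48 (m103 control 3, second salt 2) and 47 (agami salt 2). Control comparisons ran from 2805 to 4142 for agami against m103, from 3227 to 4987 between ir29-labelled sets and from 9995 to 11043 between ir29-labelled sets and japonica.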

Other observations

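The tests of why the ir29-labelled sets differ and the counts over other splits were chosen after the calls were seen, and the tests of genes, lists and contrasts were set before any test. Averaged over the sets, several groups held single genes that changed while the group did not stand apart. Of 32 glutaredoxins and thioredoxins 7 rose and 4 fell (list adjusted p = 0.35), with GRXC1 at 1.85 ± 0.22 and GRXC10 at 1.46 ± 0.21 beside GRXC15. The salt arrays of GRXC15 lay above the control arrays in every set, though no member of this list was called in agami. GRXC1 and GRXC10 did not rise in every set. Their salt change in agami minus that in m103 was -5.72 and -4.26. Of 29 genes of sucrose metabolism and sugar transport 5 rose and 9 fell (list adjusted p = 0.52), with SWEET15 at 1.71 ± 0.13, the sucrose synthase SUS4 at 0.82 ± 0.14 and SWEET2b at -0.58 ± 0.14. Of 24 aquaporins PIP1-3 (0.79 ± 0.12) and PIP2-4 (0.51 ± 0.12) rose and NIP2-1 (-0.78 ± 0.14) and SIP2-1 fell (list adjusted p = 0.93). Among 24 potassium and sodium transport genes HAK17 rose by 1.27 ± 0.14 and HAK13 fell by 0.78 (SE 0.23), with 3 genes each way (list adjusted p = 0.78).

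Some genes of the meristem and of flowering changed while their groups did not stand apart. OSH1, a homeobox gene of the shoot meristem, rose by 0.55 ± 0.10, and 3 of 13 meristem homeobox genes rose (list adjusted p = 0.54). In the first ir29-labelled set the median of these genes was 0.43 (list adjusted p = 0.14). Among 16 MADS-box factors, which set flowering and floral organs, MADS56 fell by 0.43 (SE 0.045) and MADS14 by 0.41 (SE 0.097), MADS17 rose by 0.43 ± 0.14, and in all 3 rose and 2 fell (list adjusted p = 0.82). The clock and photoperiod list, in contrast, was called for the mean of the sets (list adjusted p = 0.046, and adjusted p = 0.27 with an estimated correlation). Of the clock genes, GI was at -1.12, -1.36, -1.63 and -0.63 in m103, agami, the first and the second ir29-labelled set, and CCA1 at 0.72, 0.65, 0.34 and 0.83. Of 53 protein phosphatases 2C 6 rose and 11 fell (list adjusted p = 0.54), and of 21 abscisic acid genes 5 rose and 2 fell (list adjusted p = 0.74).

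The ir29-labelled sets differed without salt in 4672 probe sets, and 542 separated all 6 arrays of each set by at least 4-fold, against 501 between m103 and agami, a ratio of 1.08. As the main source of the 542, a batch that also parts agami from m103 is argued against. Only 12.4% of them were called in the same direction there and 9.78% in the opposite one. Over all tested probe sets 11.4% were called there in either direction, and r of the control differences was 0.05. A weaker shared batch stays open, since the second principal component (12.7%) parted agami and the second set from m103 and the first. The authors' scaling is argued against too, since 3464 calls were left with the scaling state as a covariate. As a hypothesis, the sets may be 2 cultivars under 1 name, and a batch particular to the second set stays open. The arrays do not say which set would be which cultivar.

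Other splits of the arrays bear on the remaining counts. In comparisons of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 3039 and 3 in m103, 321 and 2 in agami, 1993 and 20 in the first and 3034 and 511 in the second ir29-labelled set, 3915 and 2 between agami and m103 controls, and 4672 and 1 between the ir29-labelled controls, with only 1 split, the real one, as large in each. For the mean of the sets only the real split of 100 gave 6097, with 13 as the highest other, so chance can be excluded. For ir29-labelled against japonica controls only the real 1 of 100 gave 10997, with 3494 as the highest other. These splits exchanged control arrays among all sets, and the sets also differ within each side. With so few sets per side they cannot exclude chance differences between sets, so no conclusion is drawn from them.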
